A study of Homo sapiens with 11 samples.

How the data were processed

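Messenger RNA of MCF-7 breast cancer cells was sequenced in 11 libraries, 5 transfected with an siRNA against AHR and 6 with a non-specific control RNA, each at 50 nM for 36 hr. Per the labels, total RNA was purified on columns and treated with DNase, libraries were made with a TruSeq protocol, and paired-end reads were taken on a HiSeq instrument. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.6, Bowtie 0.12.8, DESeq without a version, and the hg19 genome.

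The authors deposited a table of raw counts per Ensembl gene, which their counting code made from the TopHat alignments. Per that deposited code, each count is an alignment whose range, from its first to its last aligned base, overlaps any transcript of the gene from end to end. Introns are therefore included, the strand is ignored, an alignment that touches several genes is counted in each, mates count singly and alignments to several places are kept. The authors also deposited a table of changed genes at a false discovery rate below 10%. In that deposited table the signal values are the authors' mean normalized counts, over both groups and for each group, after division by size factors, and the control means matched the counts only with control replicate 3 left out. Its ratio column holds the authors' fold of knockdown over control means, and its log2 column holds the log2 of the same deposited ratio. Its last columns hold the authors' p-value and the p-value adjusted for multiple tests.

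All tests were run on the deposited counts with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0 in R 4.3.3, and tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Library totals ranged from 40606533 to 79170900 counts in the knockdown group and from 58000416 to 136964032 counts in the control group, and 3 counts correspond to 0.0219 to 0.0739 CPM. Genes were kept by the default filter of edgeR, with a minimum count of 10 and a minimum total of 15, which left 27680 of 57605 identifiers. Counts were scaled by TMM, CPM values are TMM-scaled, and log2 CPM values used a prior count of 2. The groups were compared with the edgeR quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. SE values of log2 ratios were taken from the ratio and its F statistic. AHR was also compared with an exact two-sided permutation test of mean log2 CPM over all 462 groupings.

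Of the identifiers, 38427 were named from a table of gene names, 10506 only from GENCODE release 29, 39 only from the authors' deposited table, and 8633 stayed without a name. GENCODE release 29, on the genome build after hg19, served for names and for which genes overlap or lie side by side, and no coordinates are given. Because the strand was ignored and introns were counted, a named gene that overlaps another shares counts with it.

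The test, the gene lists and the rule for named genes were fixed before the data were examined. The rule named AHR, then up to 12 genes with the largest rise and 12 with the largest fall among genes past the threshold that had a mean log2 CPM of at least 1 and non-overlapping groups. From each list it named up to 4 members with the smallest adjusted p below 0.05 or, where none passed, the 2 most abundant. It always named CYP1A1, CYP1B1, AHRR, TIPARP, ARNT, NQO1, PTGS2, PTGES, PLA2G4A, TNF, TNFRSF1A, NFKBIA, ESR1, MKI67 and IFIT1. Other genes in the text were chosen after their values were seen, and are said to be so where they appear.

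The 26 lists covered AHR targets, the AHR complex, eicosanoid synthesis and breakdown, eicosanoid receptors, TNF superfamily ligands and receptors, TNF receptor signalling, NF-kB targets, oestrogen receptor targets, proliferation, p53 targets, interferon-stimulated genes, NRF2 targets, cholesterol synthesis, fatty acid synthesis, ATF4 and the unfolded protein response, hypoxia, tryptophan and kynurenine metabolism, conjugating transferases, mesenchymal, luminal, basal, fibroblast and leukocyte genes, mitochondrially encoded genes, immediate early genes and the RNA interference machinery. Of their 687 entries 683 matched an identifier, and CCL5, SRXN1, ACACA and GSTT1 did not. Each list with at least 5 measured members was tested against all other genes with camera at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the data and with fry, which tests whether a list moves on balance in one direction. List levels per library are means of log2 CPM over measured members, minus the mean over the 11 libraries.

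Alternatives planned from the start were RLE and upper quartile scaling, no filter and a stricter filter (CPM above 1 in at least 5 libraries), DESeq2, limma-voom, a robust fit, replicate number as a block, each library left out in turn, a threshold of 0.01, an absolute log2 ratio of at least 1, and shared list members left out. Alternatives added after seeing the data were leaving out control replicates 4, 5 and 6 or 1, 2 and 3, 1 surrogate variable, a threshold of 0.1 and 1 member per cluster of neighbours. The labels do not state that the replicate numbers pair the groups. Replicates were compared in pairs over 19452 genes, and 0 pairs were identical. The smallest spread of a pair within a group was 2.94 times what counting alone gives.

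The tests were tested on simulated data with the group sizes and depths of this series. The quasi-likelihood test recovered 80.6% of genes changed 1.5-fold, 97% of those changed 2-fold and 100% of those changed 4-fold, with 5% false calls. The limma-voom test recovered 79.1%, 94% and 100% with 5.9% false calls, and DESeq2 recovered 86.6%, 97% and 100% with 17.7% false calls. Of 25 simulated lists without a change 0 were called. The simulated genes were drawn independently of each other, and no difference shared by several controls was built in. These rates may therefore not hold for the real libraries, where the estimated correlation was 0.501 in the AHR targets and 0.816 in the NRF2 targets.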

Results

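Gene expression was measured by RNA sequencing in MCF-7 cells, a human breast cancer line that grows in response to oestrogen, 36 hr after transfection with 50 nM of an siRNA against the aryl hydrocarbon receptor (AHR) or of a non-specific control RNA. AHR is a ligand-activated transcription factor that switches on genes of foreign-compound metabolism. The AHR knockdown group held 5 libraries and the control group 6. The deposited count table held 57605 Ensembl gene identifiers on the hg19 genome build, of which 27680 passed the filter on low counts and were tested. Library totals ran from 40606533 to 79170900 counts in the knockdown group and from 58000416 to 136964032 counts in the control group. The labels do not say whether the replicates were separate cultures, so each p-value measures only the spread between these samples. Levels are given as CPM, counts scaled to a common library size, with the SD and the number of libraries, and changes as log2 ratios of knockdown to control with their SE.

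The single comparison asked which genes change in MCF-7 cells when AHR is depleted. AHR messenger RNA fell to 24.5% of its control level. Genes that AHR is known to switch on, genes of the oxidative stress regulator NRF2 and genes of eicosanoid metabolism lay below other genes as groups in the knockdown libraries, and genes of cell division lay above them. Over all libraries each of these set calls was lost with an estimated correlation between genes, at adjusted p of 0.217 to 0.292. The size of the group differences was not uniform over the controls: control replicates 4, 5 and 6 lay farther from the knockdown libraries than control replicates 1, 2 and 3 did. With an estimated correlation all of these lists passed without control replicates 1, 2 and 3, at adjusted p of 6.25e-05 to 7.57e-04. Without control replicates 4, 5 and 6, AHR targets (0.00213) and NRF2 targets (0.0228) passed so, while eicosanoid (0.115) and cell division genes (0.191) did not. Both settings were chosen after seeing the data, and each takes the difference between the control sets out of the spread. Their p-values therefore do not cover that difference, and the fit without control replicates 1, 2 and 3 cannot part it from the knockdown. AHR and the antisense transcript that overlaps it were the 2 genes that passed the test over all genes.

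AHR (ENSG00000106546, chromosome 7) stood at 12.4 ± 0.757 CPM (SD, n = 5) in the knockdown libraries and at 50.6 ± 3.00 CPM (SD, n = 6) in the controls, which is 4.08-fold lower. The log2 ratio was -2.03 (SE 0.06), with an adjusted p of 3.83e-10 from the edgeR quasi-likelihood test over all genes. An exact two-sided permutation test of AHR alone gave p = 0.00216, the smallest that the 462 groupings of these libraries can give. The knockdown libraries ran from 11.2 to 13.3 CPM and the controls from 45.7 to 54.9 CPM, so the ranges did not meet. AC073332.1 (ENSG00000237773), a gene annotated on the opposite strand within AHR, fell from 5.01 ± 1.25 CPM (SD, n = 6) to 1.27 ± 0.358 CPM (SD, n = 5), a log2 ratio of -2.00 with an adjusted p of 0.00191. The counts were made without regard to strand, so the counts of AC073332.1 include AHR's own and its fall is not a separate result.

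**Figure D1:**
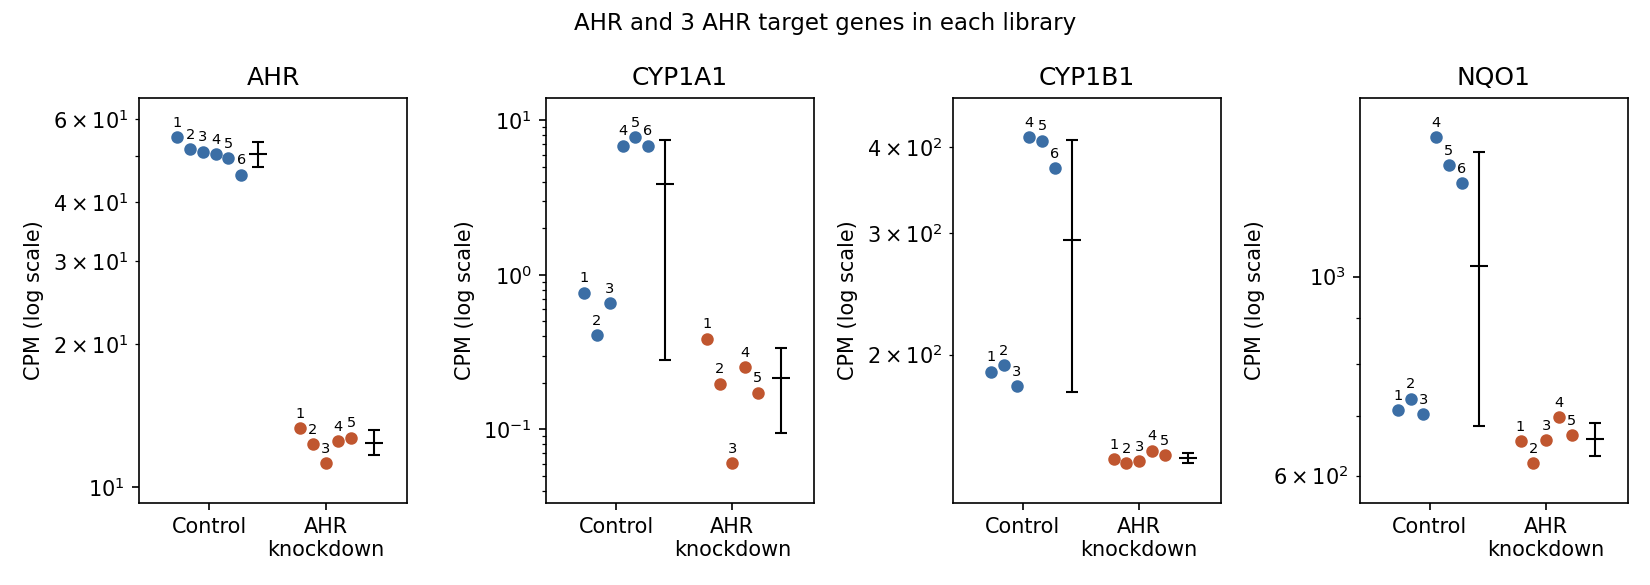
CPM of AHR, CYP1A1, CYP1B1 and NQO1 in each library on log axes, with control libraries in blue, AHR knockdown libraries in orange, replicate numbers above the points and the mean ± SD of each group in black. AHR stands at 11.2 to 13.3 CPM in the knockdown libraries and 45.7 to 54.9 CPM in the controls, while CYP1A1 in the controls ranges from 0.408 to 7.77 CPM.

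Over all genes, 0 rose and 2 fell with the edgeR quasi-likelihood test at an adjusted p below 0.05, while 5163 genes had an unadjusted p below 0.05, 2282 of them higher and 2881 lower. The limma-voom test also called 0 higher and 2 lower, and DESeq2 called 298 higher and 634 lower. The groups did not overlap at all in 387 genes that were higher and 411 that were lower in the knockdown libraries. If all libraries were interchangeable, chance would give 0.43% of genes in both directions together. The controls fell into separate sets, as described below, so that share is too low a baseline and the excess does not measure an effect of the knockdown. At the authors' false discovery rate of 10%, the edgeR test added 4 higher genes and 1 lower one: ESR1, which encodes the oestrogen receptor, with SMIM13, PSKH1, NPNT and the lower KIAA1191, the last 4 of these named after their values were seen.

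The spread between control libraries was wide. On the first principal component, which held 27.2% of the variance, the knockdown libraries lay between -25.6 and -17.4. Control replicates 1, 2 and 3 lay between -11.2 and -8.6, and control replicates 4, 5 and 6 between 40.0 and 48.6. Replicates 4, 5 and 6 were therefore left out together, and then replicates 1, 2 and 3, both chosen after seeing the data. Either choice takes the difference between the control sets out of the spread, so its p-values do not cover that difference. Without replicates 4, 5 and 6, 7 genes rose and 31 fell. Without replicates 1, 2 and 3, 3252 rose and 3945 fell. Leaving out control replicate 1 alone gave 2 higher and 27 lower, and leaving out control replicate 6 alone gave 2 higher and 4 lower. The second component, with 15% of the variance, parted the libraries across the groups. Knockdown replicate 2 lay at -42.3, control replicate 1 at -28.6 and control replicate 6 at -23.8, and the other libraries lay between 4 and 20.5. The cause of this was not tested.

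**Figure D2:**
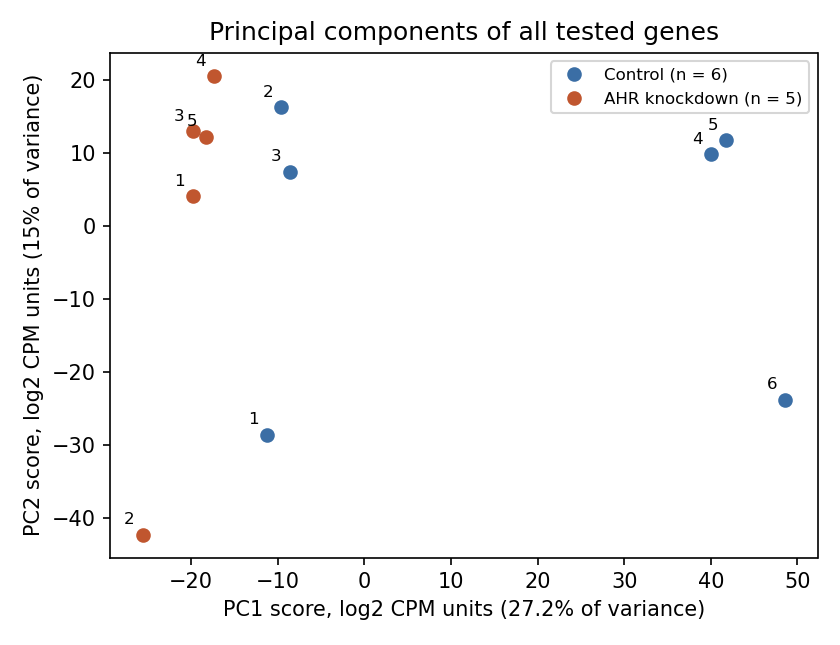
Scores of the 11 libraries on the first 2 principal components of log2 CPM over all tested genes, with replicate numbers beside the points and the share of variance on each axis. The knockdown libraries lie between -25.6 and -17.4 on the first component, control replicates 1, 2 and 3 between -11.2 and -8.6, and control replicates 4, 5 and 6 between 40.0 and 48.6. On the second, knockdown replicate 2 lies at -42.3, control replicate 1 at -28.6 and control replicate 6 at -23.8, and the other libraries between 4 and 20.5.

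Known AHR target genes lay below other genes as a group, by a set test that was lost with an estimated correlation (adjusted p = 0.217). Of 13 listed targets, 10 were measured, with a median log2 ratio of -0.85, and 8 of the 10 fell at an adjusted p below 0.05 when adjusted over the list alone. CYP1A1, the foreign-compound oxidase most often used as a readout of AHR, stood at 0.214 ± 0.12 CPM (SD, n = 5) against 3.88 ± 3.60 CPM (SD, n = 6), a log2 ratio of -4.20 (SE 0.89). The related oxidase CYP1B1 stood at 142 ± 2.28 against 293 ± 117 CPM (log2 ratio -1.05, SE 0.23), and the quinone reductase NQO1 at 659 ± 27.8 against 1028 ± 347 CPM (log2 ratio -0.64, SE 0.19). The others that fell over the list alone were ALDH3A1, an aldehyde dehydrogenase, at -3.87, UGT1A1 at -1.54 and UGT1A6 at -1.49, AHRR, the repressor of AHR, at -0.19 and NFE2L2, which encodes NRF2, at -0.14. ALDH3A1, UGT1A1, UGT1A6 and NFE2L2 were named after their values were seen, and the UGT1A genes overlap and share counts. TIPARP, a further target, stood at 20.9 ± 1.40 against 20.5 ± 1.00 CPM, with a log2 ratio of 0.03 and an adjusted p of 0.788.

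CYP1B1 is overlapped by 3 other counted genes and NQO1 and ALDH3A1 by 1 each, so part of their counts can belong to these. The set test of the AHR targets gave an adjusted p of 5.43e-09, which was 0.217 with an estimated correlation. Adjusted over all genes tested, 0 members passed with edgeR, 8 had an unadjusted p below 0.05, limma-voom called 0 and DESeq2 called 5. The mean level of the list ran from -0.72 to -0.51 on the log2 scale in the knockdown libraries, from -0.19 to -0.02 in control replicates 1, 2 and 3 and from 1.07 to 1.15 in control replicates 4, 5 and 6. CYP1A1 showed the same steps, at 0.0602 to 0.387 CPM, 0.408 to 0.766 CPM and 6.85 to 7.77 CPM, and its lowest knockdown value rests on 4 counts. Without control replicates 4, 5 and 6, CYP1B1 fell by 0.40 (adjusted p = 7.11e-04) and ALDH3A1 fell by 1.44 (adjusted p = 7.11e-04) on the log2 scale, while CYP1A1 had a log2 ratio of -1.51 (adjusted p = 0.281) and NQO1 one of -0.12 (adjusted p = 0.435), so their ratios over all libraries rest largely on those 3 controls. With the same 3 replicates left out, the list kept its call with an estimated correlation (adjusted p = 0.00213).

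Genes of the AHR complex lay slightly above other genes by a set test that was lost with an estimated correlation (adjusted p = 0.292). Of 17 measured genes of the AHR complex and its cofactors, ARNT2, a dimerisation partner of AHR-like factors, rose over the list alone (32.0 ± 0.932 against 25.8 ± 2.04 CPM, log2 ratio 0.31) and was named after its value was seen. ARNT, the main dimerisation partner of AHR, had a log2 ratio of 0.07 and an adjusted p of 0.406 over all genes. HSP90AA1, a chaperone that holds AHR in the cytoplasm, had a log2 ratio of 0.06, and the coactivator NCOA3 one of -0.02. The list had a median log2 ratio of 0.06 and lay above other genes with an adjusted p of 0.0315, which was 0.292 with an estimated correlation and 0.158 without control replicates 1, 2 and 3. It was also above 0.05 with fry (0.0534), with a stricter filter on low counts (0.0533) and without knockdown replicate 5 (0.0547), control replicate 1 (0.0595) or control replicate 6 (0.0558).

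Genes of eicosanoid synthesis and breakdown, one of the themes in the series title, lay below other genes as a group, by a set test that was lost with an estimated correlation (adjusted p = 0.287). Of 56 listed genes 46 were measured, with a median log2 ratio of -0.19, and 16 fell while 0 rose over the list alone. PTGES, the inducible synthase of prostaglandin E, stood at 5.69 ± 0.76 CPM (SD, n = 5) against 10.4 ± 3.36 CPM (SD, n = 6), a log2 ratio of -0.87 (SE 0.20). AKR1C2, a reductase of steroids and prostaglandins, stood at 72.6 ± 1.40 against 220 ± 129 CPM, a log2 ratio of -1.60 (SE 0.36). Further members that fell over the list alone, named after their values were seen, were AKR1C1 at -1.56 and AKR1C3 at -1.69, the leukotriene hydroxylases CYP4F2, CYP4F3, CYP4F11 and CYP4F12 at -1.87 to -0.75, ALOX5, which opens leukotriene synthesis, at -0.91, MGST1 at -0.40 and HPGD, which inactivates prostaglandins, at -0.43. PTGES3, the most abundant member, stood at 235 ± 7.76 against 226 ± 16.0 CPM. PTGS2, the inducible cyclooxygenase, held 0 to 10 counts per library and PLA2G4A, a phospholipase that releases arachidonic acid, 0 to 5, so a difference in either was not detectable at this depth.

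The eicosanoid list lay below other genes with an adjusted p of 9.36e-08, and the adjusted p was 0.287 with an estimated correlation. The title was written from these same samples, so the list is not independent evidence of a direction. Adjusted over all genes tested, 0 members passed with edgeR, 22 had an unadjusted p below 0.05, limma-voom called 0 and DESeq2 called 9. The list's mean level ran from -0.25 to -0.14 in the knockdown libraries, from -0.14 to -0.07 in control replicates 1, 2 and 3 and from 0.37 to 0.51 in control replicates 4, 5 and 6. Without control replicates 4, 5 and 6, AKR1C2 fell by 0.49, AKR1C1 by 0.46 and AKR1C3 by 0.42 on the log2 scale. PTGES had a log2 ratio of -0.37 and an adjusted p of 0.31 there, and the list did not pass with an estimated correlation (adjusted p = 0.115). The AKR1C genes are neighbouring paralogs, and the 46 measured genes lay in 39 clusters of neighbours. Eicosanoid receptors showed no such difference: of 8 measured, 0 passed over the list alone with edgeR, 1 had an unadjusted p below 0.05, and limma-voom and DESeq2 called 0. Their median log2 ratio was -0.12, while the set test pointed upward with an adjusted p of 0.929. LTB4R2 and LTB4R, receptors of leukotriene B with the highest counts among them, had log2 ratios of 0.12 and 0.05. They overlap each other, and LTB4R2 also overlaps NOP9 and CIDEB. Their counts are therefore shared, and the ratios are not separate results.

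Ligands and receptors of the tumour necrosis factor (TNF) superfamily, the other theme in the title, lay below other genes in the set test with an adjusted p of 0.00502, which was 0.217 with an estimated correlation, 0.111 without control replicates 1, 2 and 3 and 0.0721 with 1 member kept per cluster of neighbours. TNF signalling genes and NF-kB targets did not pass the set test. Of 38 listed ligands and receptors 22 were measured, with a median log2 ratio of -0.15, and 5 fell and 0 rose over the list alone. These were TNFRSF21, a death receptor, at 46.5 ± 0.854 CPM (SD, n = 5) against 63.8 ± 9.25 CPM (SD, n = 6) with a log2 ratio of -0.46 (SE 0.09), TNFRSF11B, a decoy receptor, at -0.68, TNFRSF10D, also a decoy receptor, at -0.52, the death receptor FAS at -0.40 and TNFRSF1A, the main receptor of TNF, at -0.29. All but TNFRSF1A were named after their values were seen. LTBR, the most abundant member, stood at 145 ± 6.70 against 164 ± 17.0 CPM. TNF itself was scarce, at 0.263 ± 0.0818 against 0.218 ± 0.0973 CPM, with a log2 ratio of 0.27 and an adjusted p of 0.691.

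Like the eicosanoid list, the TNF superfamily was named in the title from these samples and is not independent evidence. Adjusted over all genes tested, 0 members passed with edgeR, 8 had an unadjusted p below 0.05, limma-voom called 0 and DESeq2 called 3. Its mean level ran from -0.10 to -0.04 in the knockdown libraries and from -0.03 to 0.16 in the controls. TNFRSF21 also fell without control replicates 4, 5 and 6, by 0.26 on the log2 scale (adjusted p = 0.0353), while the list did not pass with an estimated correlation there either (adjusted p = 0.284). Of 44 measured components of TNF receptor signalling, 0 passed over the list alone with edgeR, 5 had an unadjusted p below 0.05, limma-voom called 0 and DESeq2 called 1, and the set test gave an adjusted p of 0.87 around a median of 0.01. Of 25 measured NF-kB targets 0 passed, 4 had an unadjusted p below 0.05, limma-voom and DESeq2 called 0, and the set test gave 0.848, with a median of 0.02 and a mean of -0.03. NFKBIA, the inhibitor of NF-kB that belongs to both lists, stood at 112 ± 5.88 against 137 ± 21.8 CPM, with a log2 ratio of -0.30 and an adjusted p of 0.159 over all genes. IKBKG, the scaffold of the kinase that releases NF-kB, had a log2 ratio of -0.35, and SOD2, a mitochondrial superoxide dismutase, one of 0.03.

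**Figure D3:**
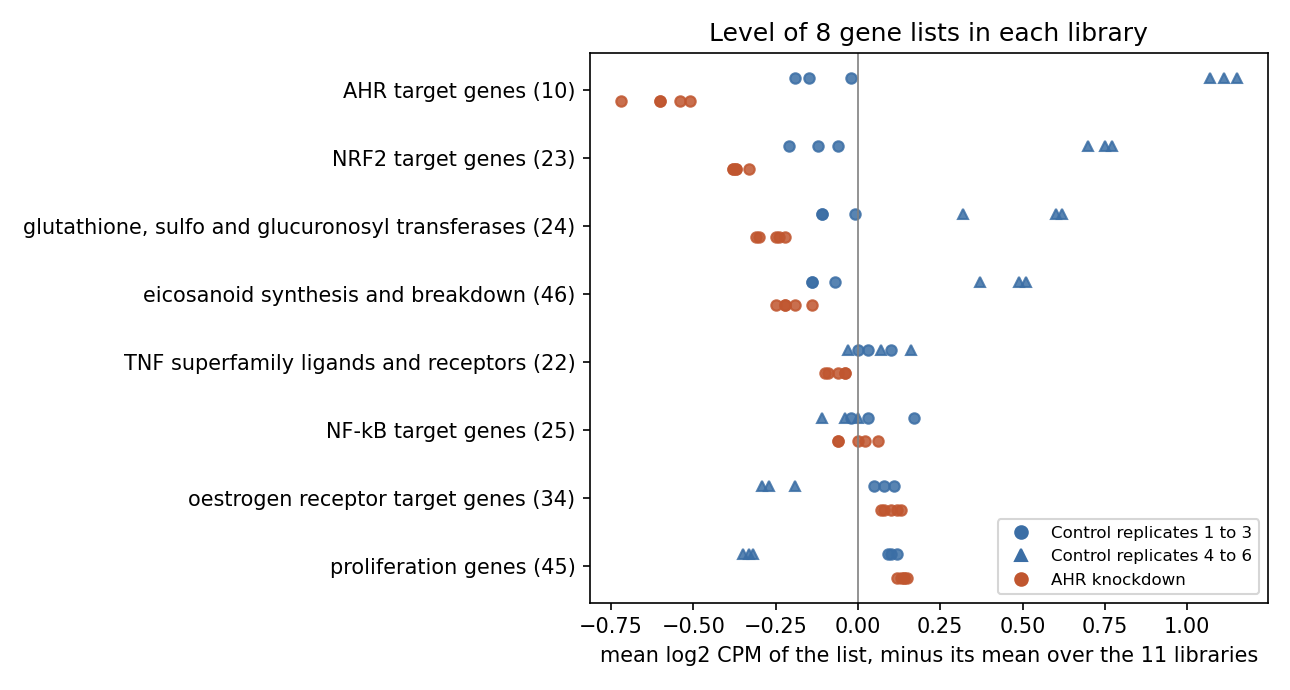
Mean log2 CPM of 8 gene lists in each library, minus the list's mean over the 11 libraries, with measured members in brackets, control replicates 1 to 3 as blue circles, 4 to 6 as blue triangles and AHR knockdown as orange circles. AHR target genes stand at -0.72 to -0.51 in the knockdown libraries, -0.19 to -0.02 in control replicates 1 to 3 and 1.07 to 1.15 in replicates 4 to 6.

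Targets of NRF2, the regulator of the response to oxidative stress, differed in one direction: of 23 measured, 22 fell over the list alone and all 23 had a log2 ratio below 0, with a median of -0.57. FTH1, the heavy chain of ferritin, stood at 1028 ± 58.2 CPM (SD, n = 5) against 1597 ± 539 CPM (SD, n = 6). HMOX1, which breaks down haem, stood at 12.7 ± 0.382 against 52.2 ± 39.3 CPM (log2 ratio -2.04, SE 0.50), and SLC7A11, the cystine importer, at 10.2 ± 0.61 against 22.3 ± 10.3 CPM, both named after their values were seen. NQO1 belongs to this list and to the AHR targets, and AKR1C1 and AKR1C2 to this list and to the eicosanoid list. Of 24 measured glutathione, sulfo and glucuronosyl transferases, which conjugate foreign compounds and hormones, 14 fell and 0 rose over the list alone, with a median of -0.49. Among these were 6 UGT1A genes that share counts, and the catechol methyltransferase COMT, whose log2 ratio was -0.32, while SULT1A3 had one of -0.04.

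The NRF2 targets lay below other genes with an adjusted p of 1.43e-21 and the transferases with 7.39e-09, and both adjusted p were 0.217 with an estimated correlation. Adjusted over all genes tested, 0 members of either passed with edgeR or limma-voom, 22 and 14 had an unadjusted p below 0.05, and DESeq2 called 15 and 7. The mean level of the NRF2 targets ran from -0.38 to -0.33 in the knockdown libraries, from -0.21 to -0.06 in control replicates 1, 2 and 3 and from 0.70 to 0.77 in control replicates 4, 5 and 6. That of the transferases ran from -0.31 to -0.22, from -0.11 to -0.01 and from 0.32 to 0.62. Without control replicates 4, 5 and 6, the median of the NRF2 targets was -0.15 and both lists kept their call with an estimated correlation, at adjusted p of 0.0228 and 0.0241.

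Genes of cell division lay above other genes as a group, by a set test that was lost with an estimated correlation (adjusted p = 0.292). All 45 listed proliferation genes were measured and had a log2 ratio above 0, with a median of 0.23, and 1 rose over the list alone: RRM2, a subunit of ribonucleotide reductase, at 198 ± 3.27 CPM (SD, n = 5) against 150 ± 25.8 CPM (SD, n = 6), named after its value was seen. The proliferation antigen MKI67 had a log2 ratio of 0.29 (SE 0.08) and an adjusted p of 0.14 over all genes, and MCM7 and MCM4, subunits of the replicative helicase, had log2 ratios of 0.20 and 0.22. The set test gave an adjusted p of 2.54e-18, which was 0.292 with an estimated correlation. Its mean level ran from 0.12 to 0.15 in the knockdown libraries, from 0.09 to 0.12 in control replicates 1, 2 and 3 and from -0.35 to -0.32 in control replicates 4, 5 and 6. Without the last 3 the median was 0.03 and the adjusted p was 0.191 with an estimated correlation.

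Oestrogen receptor targets lay above other genes with an adjusted p of 2.53e-05, which was 0.307 with an estimated correlation and 0.365 without control replicates 4, 5 and 6. Of the 34 measured, 0 passed over the list alone with edgeR, 13 had an unadjusted p below 0.05, limma-voom called 0 and DESeq2 called 2, around a median log2 ratio of 0.14. CTSD, a lysosomal protease, had a log2 ratio of 0.08 and CCND1, cyclin D1, one of 0.09. ESR1, the oestrogen receptor gene, stood at 430 ± 7.31 CPM (SD, n = 5) against 351 ± 20.7 CPM (SD, n = 6), a log2 ratio of 0.29 (SE 0.045) with an adjusted p of 0.085 over all genes, which was 0.0472 without control replicate 1. ESR1 belongs to the luminal epithelial list, of which 23 genes were measured around a median of 0.00. Over that list alone ESR1 rose, and the repressor OVOL1 at -0.26 and the claudin CLDN4 at -0.31 fell, both named after their values were seen. The keratins KRT8 and KRT18, which overlap and share counts, had log2 ratios of -0.02 and 0.04. The set test of the luminal list gave an adjusted p of 0.531.

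Targets of p53 and interferon-stimulated genes lay slightly below other genes by set tests that were lost with an estimated correlation (adjusted p = 0.217 and 0.345). Of 23 measured p53 targets FAS fell over the list alone, and the median log2 ratio was -0.10. CDKN1A, the cell cycle inhibitor p21, had a log2 ratio of -0.24 and MDM2, which degrades p53, one of 0.14. The set test gave an adjusted p of 0.0271, which was 0.217 with an estimated correlation, 0.124 without control replicates 4, 5 and 6, 0.0539 without knockdown replicate 4 and 0.0752 with genes shared between lists left out. Of 29 measured interferon-stimulated genes 3 fell over the list alone, namely OAS1 at -2.74, BST2 at -0.74 and IRF9 at -0.34, named after their values were seen, with a list median of -0.12. STAT1 and EIF2AK2 had log2 ratios of 0.10 and 0.16, and IFIT1 one of -1.01 at 0.232 ± 0.167 against 0.446 ± 0.419 CPM, which was -0.42 without control replicate 4 and -1.44 without knockdown replicate 3. Their set test gave an adjusted p of 0.0218, which was 0.345 with an estimated correlation, 0.58 without control replicates 4, 5 and 6, 0.0756 without control replicate 4 alone, 0.146 with 1 surrogate variable, 0.13 with fry and 0.0875 with a stricter filter on low counts.

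Among metabolic and stress lists, cholesterol synthesis lay below other genes with an adjusted p of 0.00631, which was 0.423 with an estimated correlation, and without control replicates 4, 5 and 6 its set test pointed upward (adjusted p = 0.734). Of its 23 measured genes 0 passed over the list alone with edgeR, 2 had an unadjusted p below 0.05, limma-voom called 0 and DESeq2 called 1, and DHCR24 and LSS had log2 ratios of -0.06 and -0.09. Of 23 measured fatty acid synthesis genes the desaturase SCD and the acyltransferase GPAM rose over the list alone, at 0.13 and 0.32, and ELOVL1, ME1 and DGAT2 fell, at -0.25, -0.49 and -0.75, all but SCD named after their values were seen, with FASN at -0.05 and a set test at 0.531, which was 0.0146 without control replicates 1, 2 and 3. That call was lost with an estimated correlation (adjusted p = 0.0592). Of 27 measured genes of ATF4 and the unfolded protein response SLC7A11 fell over the list alone, the chaperone HSPA5 and the factor XBP1 had log2 ratios of 0.20 and 0.34, and the set test gave an adjusted p of 0.315. That list pointed downward without control replicates 4, 5 and 6 (adjusted p = 0.00145) and upward without control replicates 1, 2 and 3 (adjusted p = 4.78e-04). With an estimated correlation the downward call was lost (adjusted p = 0.3) and the upward one was kept (adjusted p = 0.0215). Of 24 measured hypoxia-inducible genes the lipase inhibitor ANGPTL4 and the aldolase ALDOC fell over the list alone, at -0.57 and -0.29, both named after their values were seen, with PGK1 at 0.00, LDHA at -0.06 and a set test at 0.0953. Of 14 measured genes of tryptophan and kynurenine metabolism KYNU, MAOA and KMO fell over the list alone, at -0.31, -0.74 and -0.44, and KYAT3 rose at 0.17, of which only KYNU was named by the rule, with SLC3A2 at 0.07 and a set test at 0.0953, which was 0.0106 without control replicates 1, 2 and 3. The latter call was lost with an estimated correlation (adjusted p = 0.0937).

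Lists for other cell types and states did not pass the set test. Of 23 measured mesenchymal genes 0 passed over the list alone with edgeR, 6 had an unadjusted p below 0.05, limma-voom called 0 and DESeq2 called 2, with ITGB1 at 0.09, THBS1 at 0.15 and a set test at 0.87. Of 14 measured basal epithelial markers CAV1 rose at 0.38 and ITGA6 at 0.37 and KRT17 fell at -0.46 over the list alone, all named after their values were seen, with ITGB4 at -0.08, KRT5 at 0.16 and a set test at 0.315. Of 12 fibroblast markers 4 were measured, too few for the set test, and COL1A1 and FBN1 had log2 ratios of 0.04 and -0.53. Of 8 measured leukocyte markers 0 passed over the list alone with edgeR, 0 had an unadjusted p below 0.05, and limma-voom and DESeq2 called 0. CSF1R and CD19 had log2 ratios of -0.06 and 0.04, with a set test at 0.688. KRT5 and CD19 each had a neighbour, not overlapping, with nearly equal counts in every library, so their counts may not be their own. Of 22 measured immediate early genes 0 passed with edgeR, 1 had an unadjusted p below 0.05, limma-voom called 0 and DESeq2 called 1, with JUNB at -0.17, IER2 at -0.13 and a set test at 0.659, which was 1.49e-04 without control replicates 4, 5 and 6 and 0.00456 with 1 surrogate variable, both downward. The call without control replicates 4, 5 and 6 was lost with an estimated correlation (adjusted p = 0.347).

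All 13 mitochondrially encoded genes were measured, with MT-CO1 at 0.07 and MT-CO2 at 0.11, 0 past the test or an unadjusted p below 0.05 with edgeR, 0 by limma-voom or DESeq2, and a set test at 0.0651. Mitochondrial transcripts took 1.03% of the counts in control replicate 4 and 1.87% to 2.18% in the other 10 libraries. Without control replicate 4 the set test pointed downward (adjusted p = 0.949). It gave adjusted p of 0.0169 with no filter on low counts, 0.0355 without knockdown replicate 3, 0.00791 without control replicate 5, 0.00486 without control replicate 6 and 0.00201 without control replicates 4, 5 and 6, all upward. With an estimated correlation it gave 0.738 over all libraries and 0.397 without control replicates 4, 5 and 6. These 13 genes lie in 1 cluster of neighbours. The 13 measured genes of the RNA interference machinery lay above other genes around a median of 0.10, with an adjusted p of 0.0445 that was 0.217 with an estimated correlation. It was between 0.0513 and 0.0888 without knockdown replicate 1 or 5 or control replicate 1, 2, 3, 5 or 6. It was 0.0647 with a stricter filter on low counts, 0.0887 with 1 member kept per cluster of neighbours, and 0.0927 and 0.24 without control replicates 4 to 6 and 1 to 3. Of these 0 passed over the list alone with edgeR, 5 had an unadjusted p below 0.05, and limma-voom and DESeq2 called 0, with DICER1 at 0.01 and XPO5 at 0.12.

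A set of 36 genes was called with either set of 3 control replicates left out and in the same direction, named after their values were seen. Of these 6 rose and 30 fell, out of 27721 genes tested both times, while independent calls would share 0.82 and 4.34. They are fewer separate results than genes: 32 could be placed and lay in 22 clusters of neighbours within 100 kb, the largest of which held 7 genes around AKR1C1. All but AHR and AC073332.1 failed the test with all libraries. Besides AHR, the genes that fell include AHR targets (CYP1B1 and ALDH3A1), NRF2 targets (HMOX1, AKR1C1, AKR1C2 and ABCC3), the drug exporter ABCG2, the circadian repressor BHLHE41, the carboxypeptidase inhibitor LXN and the sialyltransferase ST3GAL1. The log2 ratios of these 4 were -0.60, -0.62, -0.53 and -0.28 without control replicates 4, 5 and 6, and -1.88, -1.85, -1.53 and -1.09 without control replicates 1, 2 and 3. UGCG, which makes glucosylceramide, fell by 0.28 and 0.17 in the same comparisons, with a narrower control spread, at 47.3 ± 1.33 CPM (SD, n = 5) against 55.2 ± 2.74 CPM (SD, n = 6). The 6 that rose were ESR1 at 0.23 and 0.34, TACC1 at 0.27 and 0.26, NPNT at 0.28 and 0.23, SMIM13 at 0.32 and 0.40 and the overlapping pair PSKH1, at 0.46 and 0.30, and CTRL, at 0.45 and 0.29, in the same order. Overlaps on opposite strands also link LXN with GFM1 and ALDH3A1 with AC005722.3, so these pairs are not separate results. The knockdown libraries were the same in both tests, so part of the excess may come from them. In 20 simulations without any change 0.05 genes were shared on average and at most 1. Those simulations held no difference between the control libraries, so few calls were due in either test and they cannot measure that part. The 20 ways of parting the knockdown libraries too shared 1 to 17 genes, with a median of 5 against 0.6 from independent calls. These counts leave out neither AHR, the target of the siRNA, nor genes that share counts. The excess therefore does not measure how far a response beyond AHR was shared.

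The authors' deposited table of changed genes held 634 genes at a false discovery rate below 10%, of which 254 were higher and 380 lower after knockdown. In the authors' deposited table AHR was 4.07-fold lower, CYP1A1 21.1-fold lower, ALDH3A1 16.8-fold lower and CYP1B1 2.23-fold lower, while ESR1 was 1.24-fold higher. The authors' deposited table listed as lower 12 NRF2 targets, 8 eicosanoid genes, 6 transferases, 5 AHR targets and 3 TNF superfamily receptors (FAS, TNFRSF11B and TNFRSF21), and as higher 10 proliferation genes. Both genes called here were in the authors' deposited table with the same direction. The overlap of the authors' deposited table with the DESeq2 calls was 402 genes, with the calls made without control replicates 4, 5 and 6 it was 28, and with those made without control replicates 1, 2 and 3 it was 614. All draw on the same 11 libraries, some with controls left out, so the overlap is not replication. All 634 control means in the authors' deposited table matched the counts, within a relative difference of 1e-06, when control replicate 3 was left out, and 0 did with all 11 libraries.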

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

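The tests of sequencing depth and of GC content and transcript length were written before their results were seen, while the test of the library labels, both tests of neighbouring genes and both counts of other splits were chosen after.

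Single libraries lay far from the rest of their group in 12 of 126 groups of values examined, where chance marks about 1 in 20, or 6.3. In knockdown replicate 2, HSP90AA1 stood at 1500 CPM (1610 to 1650 in the other knockdown libraries), HSPA5 at 568 CPM (595 to 604), CTSD at 1120 CPM (955 to 998), CCND1 at 716 CPM (626 to 651) and ITGB4 at 513 CPM (450 to 465). In knockdown replicate 5 ARNT stood at 74.9 CPM (72.9 to 73.1), and in knockdown replicate 1 PTGES stood at 7.02 CPM (5.20 to 5.51). The 5 marked values among the controls all belonged to control replicate 4. In it mitochondrially encoded genes took 1.03% of the counts (1.87% to 2.18% in the other controls), MT-CO1 stood at 1700 CPM (2950 to 3440), MT-CO2 at 1390 CPM (2910 to 3380), the leukotriene receptor LTB4R at 19.8 CPM (32.0 to 37.7) and COL1A1 at 11.7 CPM (15.9 to 18.9).

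Control replicates 4, 5 and 6 lay apart from control replicates 1, 2 and 3 by 48.7 log2 units on the first principal component, where the knockdown libraries spanned 8.19. Unequal depth is argued against, since the gap was 50.9 after every library was thinned to the smallest total, 40606533 counts, with a knockdown range of 4.49. A bias with GC content or transcript length is argued against as the whole cause, since on the 91% of tested genes with both values the gap was 46.5 before and 47.1 after removing each library's trend, which held 0.403% to 10.1% of its variance. Knockdown libraries under a control label are argued against, since the lowest AHR level in control replicates 4, 5 and 6 was 45.7 CPM and the highest in the knockdown libraries 13.3 CPM. No label gives a meaning that separates these replicates, although the submitters' own sample numbers run on without a gap in control replicates 1, 2 and 3 and skip before and within replicates 4, 5 and 6, so no biological explanation was tested, and a difference in culture, day or sequencing run stays open.

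In the authors' deposited table the largest falls, 47.5-fold to 53.1-fold, belonged to 6 identifiers on chromosome X whose counts were nearly equal in every library, at 1707 to 1709 in control replicate 4 and 3 to 18 in the knockdown libraries, but also at 5 to 7 in control replicate 1, so the groups were not separated. A candidate explanation is that alignments spanning a stretch of the chromosome were counted in each gene they crossed, as the authors' counting allows: the 10 other identifiers between the ends of the cluster rose with its counts, beside a share of the library total, at a median slope of 0.942 (9 of 10 between 0.5 and 1.5, F8 at -0.312), against 0.0409 in the 20 nearest identifiers outside. Of those 20, 2 also lay between 0.5 and 1.5 (AC234781.1 at 1.07 and TMLHEP1 at 1.02). G6PD, also outside, had a slope of 19.5, so the contrast at the ends is not complete. Reads shared among these 6 through similar transcripts are argued against, since 0 of 15 pairs of them shared at least 10% of their 31-base words. Only their annotated transcripts were compared, so reads shared with copies elsewhere or outside those transcripts stay open. Over all counted genes, 850 identifiers had a neighbour within 500 kb, not overlapping, whose counts were equal within 5% plus 2 counts in every library, and 45 of them were among the 634 in the authors' deposited table. Whether these 6 identifiers are expressed in MCF-7 cells stays open.

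The 11 libraries can be split into groups of 5 and 6 in 462 ways, of which 100 were drawn, the real one included, and in 56 ways with control replicates 4, 5 and 6 held in the control group, all of which were run. As many genes as the real 2 were called in 3 of the 100, where other splits called 17 and 6, and in 5 of the 56, where the highest other called 18. Few of the 100 reached the real count, but other splits passed it in both, so the count alone does not exclude chance. The split with 18 put control replicate 1 in place of knockdown replicate 5. Calling several times the real count points to a structure of the samples. On the second principal component control replicate 1 lay on the same side as knockdown replicate 2 and control replicate 6, apart from the other libraries. The split with 6 parted control replicates 4, 5 and 6, however, and no cause was tested. As many lists as the real 12 were called in 1 of the 100, where the highest other called 11, and in 2 of the 56, where the highest other called 13. Few splits reached the real count, but only 14 of the other drawn splits kept control replicates 4, 5 and 6 together. Those 14 called 8 to 11 lists, so the count alone does not exclude chance. The other splits of the 56 still called 8 to 13 lists with a median of 10, so much of the count can come from the difference between the controls, and with an estimated correlation 0 lists were called in the real split.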

How the results depend on the processing

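Alternatives added after the data were seen were leaving out control replicates 4, 5 and 6 or 1, 2 and 3, 1 surrogate variable, a threshold of 0.1 and 1 member per cluster of neighbours. AHR fell under all settings tried, with log2 ratios of -2.08 to -1.98, of -2.06 to -1.99 when single libraries were left out and -2.06 (adjusted p = 1.54e-06) with the replicate number as a block, a pairing the labels do not state. RLE and upper quartile scaling, both filters on low counts, limma-voom, the robust fit, a threshold of 0.01 and a log2 ratio of at least 1 each gave 0 genes higher and 2 lower.

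The counts of genes called higher and lower were 298 and 634 with DESeq2, 0 and 9 with replicate number as a block, 7 and 31 without control replicates 4, 5 and 6, 3252 and 3945 without control replicates 1, 2 and 3, and 34 and 121 with 1 surrogate variable, and 4 genes were higher at a threshold of 0.1. Leaving out single libraries gave 0 to 2 higher and 2 to 27 lower, with 27 without control replicate 1. Lists called higher numbered 2 with a stricter filter and 2 to 5 without single libraries, and lists called higher and lower numbered 0 and 0 with an estimated correlation and 1 and 3 with fry. The overlap with the authors' deposited table was 402 with DESeq2, 28 without control replicates 4, 5 and 6, 614 without control replicates 1, 2 and 3 and 106 with 1 surrogate variable.

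No pairing by replicate number was seen: correlations of knockdown and control replicates of like number ran from -0.12 to 0.025 across genes, and 0 samples correlated best with their own number. Each group was centred on its own mean only. The difference between the control sets stayed in these values and could hide a pairing, so pairing is not excluded. With the block the adjusted p was 0.0729 for the AHR complex and 0.0692 for RNA interference, which no longer passed, and 7.82e-04 for mitochondrially encoded genes, which newly passed, and it moved no other list over the threshold. For the AHR targets the adjusted p was 0.217 with an estimated correlation and 0.0534 with fry, for eicosanoid synthesis 0.287 and 0.0947, and for the TNF superfamily 0.217 with an estimated correlation, 0.111 without control replicates 1, 2 and 3 and 0.0721 with 1 member per cluster. With fry it was also 0.123 for oestrogen receptor targets, 0.0998 for proliferation, 0.0534 for NRF2 targets and transferases, 0.144 for cholesterol synthesis, which had 0.244 with 1 surrogate variable, and 0.0235 for hypoxia, which newly passed. The TNF superfamily, p53 targets and RNA interference kept their calls with fry, each at an adjusted p of 0.0382.

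Across all comparisons of a named gene with an alternative, 1234 kept direction and side of the threshold, 51 newly passed it and 54 changed direction without passing it either time. For lists 538 kept both, 50 no longer passed, 12 newly passed and 22 changed direction, 20 of these without passing either time. The cause of these changes was not tested.

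Without control replicates 4, 5 and 6 the log2 ratios that changed direction became -0.04 for HSP90AA1, 0.05 for NCOA3, -0.02 for PTGES3, -0.03 for SOD2, -0.07 for CCND1, 0.00 for MCM7, 0.03 for DHCR24, 0.07 for LSS, 0.02 for FASN, -0.05 for HSPA5, -0.01 for XBP1, -0.16 for SLC3A2, 0.02 for KRT8, 0.01 for ITGB4, -0.07 for DICER1, -0.21 for TNF and 0.27 for IFIT1. With 1 surrogate variable they became 0.04 for NCOA3, -0.01 for SOD2, -0.02 for CCND1, 0.00 for DHCR24, 0.01 for LSS and PGK1, -0.08 for SLC3A2, -0.04 for DICER1, -0.03 for TNF and 0.03 for IFIT1. SULT1A3 became 0.05 without control replicates 1, 2 and 3, KRT8 and DICER1 became 0.01 and -0.03 with the block, and PGK1 stayed at 0.00 with upper quartile scaling, DESeq2 and limma-voom. Without single libraries the ranges that crossed 0 were -0.05 to 0.02 for NCOA3, -0.06 to 0.10 for LTB4R, -0.09 to 0.00 for FASN, -0.02 to 0.02 for PGK1, -0.12 to 0.01 for SULT1A3, -0.05 to 0.01 for KRT8, -0.05 to 0.08 for COL1A1, -0.02 to 0.11 for CD19, -0.04 to 0.13 for MT-CO1, -0.03 to 0.17 for MT-CO2 and -0.04 to 0.04 for DICER1.

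Lists changed direction without control replicates 4, 5 and 6 for cholesterol synthesis (adjusted p = 0.734, upward), fatty acid synthesis (0.456, upward) and ATF4 and the unfolded protein response (0.00145, downward, which was 0.3 with an estimated correlation, and 0.235 with 1 surrogate variable). They did so without control replicates 1, 2 and 3 for TNF signalling and NF-kB targets (both 0.988, upward), leukocyte markers (0.988, downward) and immediate early genes (0.172, upward). Eicosanoid receptors turned downward with 1 surrogate variable (0.993) and with 1 member per cluster (0.965), NF-kB targets upward with no filter (0.941) and mesenchymal genes upward with a stricter filter (0.905). Without single libraries the lists that turned had adjusted p of 0.667 to 0.99 for eicosanoid receptors, 0.717 to 0.988 for TNF signalling, 0.623 to 0.988 for NF-kB targets, 0.704 to 0.988 for mesenchymal genes, 0.00486 to 0.949 for mitochondrially encoded genes and 0.237 to 0.942 for immediate early genes. Depth limits scarce genes: 3 counts were 0.0219 to 0.0739 CPM.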

Other observations

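Several oestrogen-responsive, lipid and antiviral genes, named after their values were seen, differed between control libraries. XBP1, a factor of the unfolded protein response that oestrogen induces, stood at 611 to 642 CPM in control replicates 1, 2 and 3, 340 to 362 CPM in control replicates 4, 5 and 6 and 590 to 637 CPM in the knockdown libraries. GREB1, an oestrogen-induced growth regulator, stood at 79.7 to 83.9 CPM, 43.8 to 51.5 CPM and 82.8 to 91.1 CPM in the same order, and PGR, the progesterone receptor, at 9.37 to 11.5 CPM, at most 3.98 CPM and 10.6 to 13.3 CPM. DGAT2, which completes triglyceride synthesis, went the other way, at 9.21 to 9.85 CPM, 20.7 to 21.3 CPM and 8.79 to 9.47 CPM. So did OAS1, an antiviral enzyme, at 1.33 to 1.55 CPM, 8.61 to 11.3 CPM and 0.68 to 1.09 CPM. AHR itself stood at 51.1 to 54.9 CPM in control replicates 1, 2 and 3 and at 45.7 to 50.5 CPM in control replicates 4, 5 and 6.

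Other genes were lower in every knockdown library than in every control, with little spread between controls, and were also named after their values were seen. KIAA1191 stood at 84.4 to 86.3 CPM in the knockdown libraries and 94.8 to 104 CPM in the controls. PPP2R1B, a scaffold subunit of protein phosphatase 2A, stood at 23.5 to 25.9 CPM against 27.2 to 32.5 CPM, and SLC35D1, a nucleotide sugar transporter, at 19.1 to 20.7 CPM against 21.0 to 26.4 CPM. Their adjusted p over all genes with edgeR were 0.085, 0.115 and 0.115, so none of the 3 passed the threshold of 0.05 with all libraries.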
